A study of Mus musculus with 8 samples.

How the data were processed

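RNA from the livers of 8 mice was measured on 8 arrays, 4 from mice given anti-miR-128-3p and 4 from control mice, and each array was taken as 1 mouse from the numbered titles and the group size of 4, which do not state it outright. Per the labels' protocols, total RNA was extracted with TRIzol and biotinylated for an Affymetrix array. The deposited values are on a log2 scale and were made with RMA (background correction, quantile normalization and probe summary across arrays), per the submitters' processing notes. The version of the software that ran RMA, its annotation build and any filter are not given in the sources used here. The medians of the arrays' transcript probe sets differed little, from 4.31 to 4.36, and no detection call accompanies the values.

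The table held 72688 rows, of which 6732 array control rows (negative and positive controls, spike-ins and background sets) were left out of the tests and 65956 probe sets for mouse transcripts were kept. The platform annotation used here lists 32750 of these and does not list 33206, which stay unnamed. Of those listed, 7659 kept their single symbol, 22809 had it updated through the Entrez ID against a RefSeq table of the mouse assembly GRCm38.p6 that was used for names only, 617 had several names of 1 gene, 136 had 1 symbol for several Entrez genes and 1529 named several genes. The 31085 probe sets that name exactly 1 gene gave 30633 genes, 356 of them with more than 1 probe set, for which the probe set with the highest mean over all 8 arrays was taken without regard to the groups. No genome or 3' UTR sequences were used here, so the planned test of miR-128-3p seed sites was not run and no coordinates are given. A few genes of the fixed lists had no probe set of their own and are not analysed here.

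Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, no covariate, all 8 arrays) and Benjamini-Hochberg adjustment over all 30633 genes, with a threshold of 0.05. No filter on dim genes was applied. Gene lists were tested with camera, a limma test that compares a list with the other genes, at a preset inter-gene correlation of 0.01, with adjustment over the 28 of 29 lists that had at least 5 measured genes, and the host genes of the microRNA are given as values. For each list the members past an adjusted p of 0.05 are given over all genes and over the list alone, and the list score of an array is the mean over members of the signal minus that gene's mean over the 8 arrays. Scores were compared with an exact two-sided permutation test over the 70 assignments of 4 against 4, whose smallest p is 0.0286. Of the 11 lists called by camera, 6 were higher and 5 lower, 0 were called with an estimated correlation, and fry, which tests whether a list's genes move on balance one way, called 1. Log2 differences are treated minus control, errors on them are limma's SE, and fold changes are 2 to that power. Principal components were taken over the 15317 genes at or above the median mean signal. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

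The genes named in the text follow a rule: the 12 in each direction with the smallest p among named genes whose groups do not overlap (those past the adjusted threshold first, of which there were none), predicted, pseudogene and small RNA genes being counted but not named; up to 4 members of each list described, by smallest p; and a fixed set of cholesterol genes and the microRNA's host genes. Groups, gene lists, tests, the rule and the alternatives were set before the data were examined, except where the closing section says otherwise. The steps were tested on simulated data with the same arrays, genes and spread, in which known genes among the brighter ones were changed: at 8 arrays limma recovered 70.1% of the 67 genes changed by a log2 of 0.5, 79.1% of the 67 changed by 1 and 97.0% of the 66 changed by 2, and called 5 of the 30413 unchanged genes outside the moved list, while camera called the moved list and 0 of 27 others. The simulated genes varied independently, which real genes do not. The changed genes were drawn at random among the brighter ones, so these shares are not the power for the genes named below. Usp18, for example, differed by 1.66 ± 0.26 (log2 difference ± SE) in the real data without passing (limma adjusted p = 0.194). Alternatives were moderation with a trend and robust fit, array weights, filters on dim genes at the 25th percentile and at the median, the mean of a gene's probe sets, every probe set by itself, quantile normalization, centring on the array median, the replicate number as a block, a fold threshold of 1.5 with unadjusted p, an adjusted p under 0.1, and leaving out each array in turn. Which of the uncalled lists to describe, the exact permutation of list scores with adjustment over lists, and leaving out control replicate 1 and treated replicate 3 together were chosen after the data were seen.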

Results

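Liver RNA was measured on a whole-transcript Affymetrix mouse array in 8 male C57BL/6 mice that had eaten a high fat diet for 13 weeks to raise their blood cholesterol. Of these, 4 mice had received 5 injections into the peritoneal cavity of anti-miR-128-3p, an antisense inhibitor of the microRNA miR-128-3p, and 4 control mice had received a control injection, which the labels call a vehicle in 1 place and a control in others, so that its content is not certain. The comparison asks what inhibition of miR-128-3p does to gene expression in the liver under this diet. A treatment field of the labels names miR-128-3p itself, whereas the titles and the design text name the inhibitor. The groups here follow the titles. The values were RMA log2 signals of 30633 genes, of which 19059 are annotated as protein-coding. The median signal of the 8 arrays lay between 5.04 and 5.12, against medians of 4.32 to 4.48 for the negative control rows of the same arrays. The arrays correlated with each other across genes at r = 0.992 to 0.996. With 4 arrays per group, single livers limit the precision of every value given here.

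Several of the genes with the smallest p-values were interferon-induced genes, higher in treated livers. Of the 12 genes with the smallest p-values among those higher in all 4 treated livers than in any control liver, Usp18 was higher by 1.66 ± 0.26 (log2 difference ± SE), Ifit1 by 1.61 ± 0.24, Ifit3b by 1.24 ± 0.20 and Oas2 by 1.23 ± 0.21. Of the same 12, Ifit3 by 0.99 ± 0.14, Ddx60 by 0.97 ± 0.16 and Rtp4 by 0.89 ± 0.14. The others were H2-T24 (0.68), the RNA helicase gene Dhx58 (0.67), the GTPase gene Irgm1 (0.61), the transcription factor gene Irf9 (0.44) and Parp11 (0.43). Among the 12 genes at the other end, Cd207, the langerin gene of Langerhans and some dendritic cells, was lower with a log2 difference of -1.22 ± 0.22, and Tlr5, the flagellin receptor, with -0.65 ± 0.10. Lipid phosphate phosphatase gene Plpp3 (-0.42), Spred2 (-0.36), Scamp3 (-0.35), the chloride channel gene Clcn2 (-0.34), Ftsj1 (-0.33), Tmem102 (-0.32), the histone demethylase gene Kdm6b (-0.26), the splicing factor gene Esrp2 (-0.24), Fam234a (-0.23) and Etohd2 (-0.23) were lower by smaller amounts. None of these 24 genes passed the correction over all 30633 genes: limma called 0 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.194. At an unadjusted p under 0.05 there were 2337 genes, or 7.63% of those tested against 5% expected, 1305 of them higher and 1032 lower. Groups did not overlap in 1351 genes, or 4.41% against the 2.86% that chance gives. Without control replicate 4, limma called 1 gene, Irgm1, with an adjusted p of 0.0375.

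**Figure D1:**
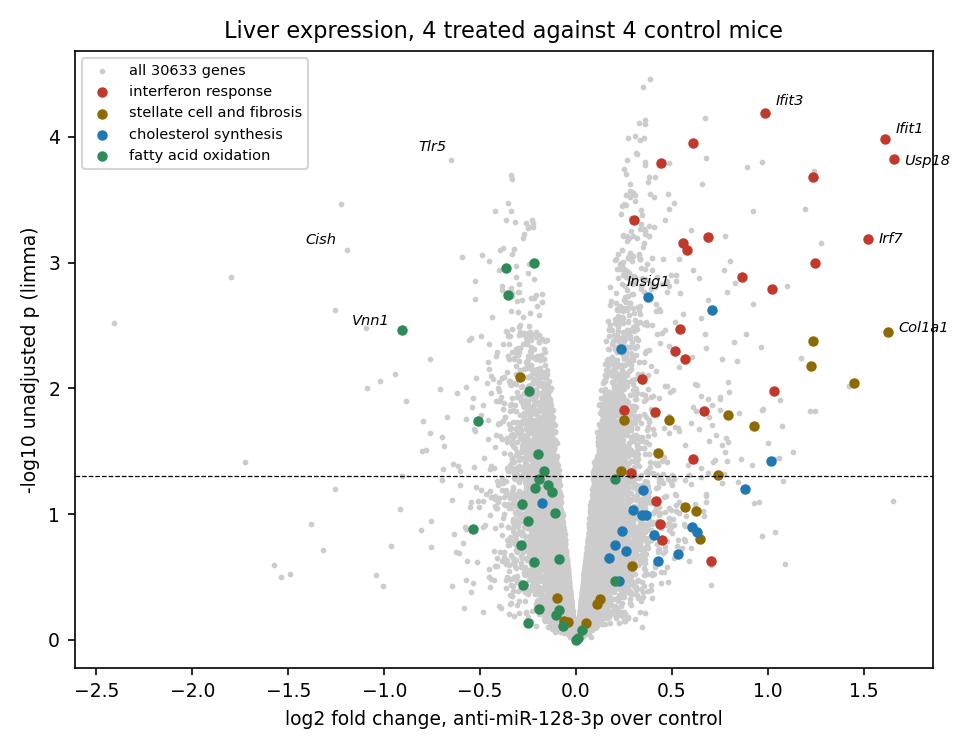
Log2 fold change of anti-miR-128-3p over control livers (horizontal axis) against -log10 of the unadjusted limma p (vertical axis), with a point for each of the 30633 genes and the members of 4 gene lists in colour. All 28 interferon response genes lie to the right of 0, with Usp18 at 1.66 and Ifit1 at 1.61. No gene passed limma's adjusted p threshold, and the dashed line marks the unadjusted threshold.

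The interferon response, the antiviral programme that cells switch on when type I interferons bind their receptor, was the gene list with the smallest camera p. All 28 measured members of the 30 listed were higher in treated livers, with a median log2 difference of 0.59. With p-values adjusted over the list alone, 23 members rose, none fell and 5 did not pass, while 0 passed over all genes tested. Ifit1, whose product binds viral RNA, was at 5.35 ± 0.36 in control and 6.97 ± 0.47 in treated livers (log2 signal, mean ± SD, n = 4 each), a 3.06-fold difference. Usp18, an interferon-induced protease that removes ISG15 and restrains interferon signalling, was at 6.22 ± 0.55 and 7.88 ± 0.32, a 3.15-fold difference. The mean list score, the mean over members of the gene-centred signal, was -0.37 ± 0.30 in control and 0.37 ± 0.22 in treated livers, and the 4 treated scores all lay above the 4 control scores (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). By camera with a preset correlation of 0.01 the list had an adjusted p of 7.98e-33, and with an estimated correlation the adjusted p was 0.111. Treated replicate 3 had the highest score, 0.69, and without it the median log2 difference was 0.52 and 21 members passed over the list alone.

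**Figure D2:**
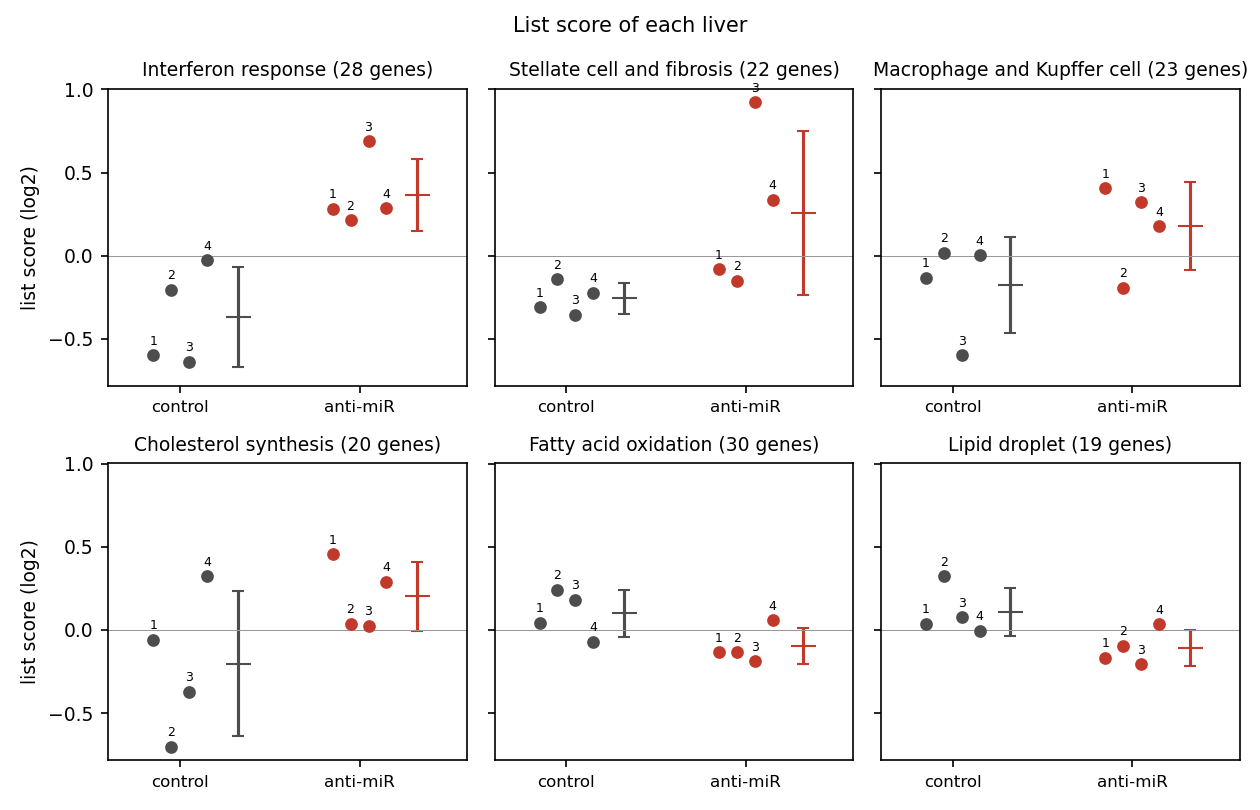
List score of each liver for 6 gene lists: the vertical axis is the mean over list members of the log2 signal after centring each gene on its mean of the 8 arrays, points are livers with their replicate numbers, and bars are the group mean ± SD (n = 4). Interferon scores did not overlap between groups, whereas the fibrosis score reached 0.92 in treated replicate 3 and -0.15 in treated replicate 2.

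Genes of cholesterol synthesis and uptake, the targets of the sterol-sensing transcription factor SREBP2, were higher in treated livers in 19 of the 20 members measured (26 listed), with a median log2 difference of 0.36. Over the list alone 3 members rose and 17 did not pass, with 0 past the threshold over all genes. Hmgcs1, the synthase of HMG-CoA, rose by 0.71 ± 0.17 (1.64-fold), Insig1, the endoplasmic reticulum protein that holds SREBP back when sterols are plentiful, by 0.37 ± 0.09 (1.29-fold), and Sc5d, a late enzyme of the pathway, by 0.24 ± 0.06. Fdps, the farnesyl diphosphate synthase, was 1.02 ± 0.42 higher and did not pass, while Srebf2 itself differed by 0.17 ± 0.13 and Fdft1 by 0.35 ± 0.17, also without passing. The list was called higher by camera (adjusted p = 9.24e-08), but its adjusted p was 0.473 with an estimated correlation. Its control scores ran from -0.70 in replicate 2 to 0.32 in replicate 4, further apart than the group means of -0.20 and 0.20. Treated scores ran from 0.03 in replicate 3 to 0.46 in replicate 1, the highest of all livers. The exact two-sided permutation p for the scores was 0.143. The number of members that rose over the list alone was 14 without control replicate 4 and 0 without control replicate 3 or without treated replicate 1. Without control replicate 2 the median was 0.23, Fdps was 0.67 higher and Srebf2 0.08, and without treated replicate 4 Srebf2 was 0.07 higher.

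Genes of cholesterol efflux, liver X receptor targets and lipoproteins were slightly lower, in 20 of the 26 members measured (32 listed), with a median log2 difference of -0.11. The 4 treated scores all lay below the 4 control scores (exact two-sided permutation p = 0.0286), with means of 0.05 ± 0.03 in control and -0.05 ± 0.04 in treated livers. The list was called lower by camera (adjusted p = 0.00227) and was the only list called by fry (adjusted p = 0.0353), whereas with an estimated correlation its adjusted p was 0.111. Over the list alone the single member that passed went the other way: Npc2, the lysosomal cholesterol carrier, rose by 0.26 ± 0.06. Lcat, the enzyme that esterifies cholesterol in plasma lipoproteins, differed by -0.23 ± 0.07, Mylip by -0.26 ± 0.09, the triglyceride transfer gene Mttp by -0.18 ± 0.06 and the cholesterol exporter gene Abca1 by -0.11 ± 0.06 (-0.07 without control replicate 2), and none of these passed. Over the list alone, 0 members rose without control replicate 2, 3 or 4 or without treated replicate 1 or 4, and 1 member fell without control replicate 1 or without treated replicate 3 or 4.

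Bile acid synthesis and transport genes were not called (23 of 23 measured, 6 higher and 17 lower, median log2 difference -0.09, camera adjusted p = 0.0544), and 0 members passed over the list alone. They were called lower without control replicate 1 (-0.15, adjusted p = 0.000514), without treated replicate 2 (-0.12, adjusted p = 0.00703) and without treated replicate 3 (-0.08, adjusted p = 0.0217). The median was -0.05 without control replicate 2 and -0.06 without treated replicate 1, and the adjusted p was 0.258 and 0.328 without control replicates 3 and 4. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 9.48 ± 0.96 in control and 10.9 ± 0.44 in treated livers (n = 4 each), a 2.68-fold difference that did not pass (limma adjusted p = 0.460 over all genes). Nr0b2, a nuclear receptor that represses Cyp7a1, was at 9.37 ± 0.35 and 8.61 ± 0.57, with no overlap between groups and an adjusted p of 0.563 by limma. Without treated replicate 4, where it was at 7.75, its difference went from -0.76 to -0.48. Abcb4, the phospholipid exporter of the bile canaliculus, differed by -0.25 ± 0.09 and the racemase gene Amacr by -0.19 ± 0.07.

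Fatty acid oxidation genes and targets of the lipid-sensing receptor PPARα were lower in treated livers in 26 of the 30 members measured (33 listed), with a median log2 difference of -0.20. Over the list alone 4 members fell, none rose and 26 did not pass, with 0 past the threshold over all genes. Vnn1, the pantetheinase gene and a PPARα target, fell by 0.91 ± 0.23 and the carnitine palmitoyltransferase gene Cpt2 fell by 0.36 ± 0.08. The carnitine-acylcarnitine carrier gene Slc25a20 fell by 0.35 ± 0.08 and Hadhb, a subunit of the mitochondrial trifunctional protein, fell by 0.22 ± 0.05. Camera called the list lower (adjusted p = 9.24e-08), with an adjusted p of 0.111 with an estimated correlation and an exact two-sided permutation p of 0.0857 for the scores. Without control replicate 2 the median was -0.12, and without treated replicate 1 the members that fell over the list alone numbered 2.

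Lipid droplet and steatosis genes were lower in 16 of 19 members, with a median log2 difference of -0.22 (camera adjusted p = 1.65e-05, adjusted p = 0.111 with an estimated correlation, exact two-sided permutation p = 0.0571 for the scores). Only Cideb, a lipid droplet and lipoprotein lipidation gene, passed over the list alone, where it fell by 0.32 ± 0.06, and 18 members did not pass. The droplet coat genes Plin4 and Plin2 differed by -0.69 ± 0.27 and -0.29 ± 0.11 and the droplet fusion gene Cidec by -0.24 ± 0.10 (-0.15 without control replicate 2). The number of members that passed over the list alone was 3 without control replicate 1, 2 without control replicate 3, and 0 without control replicate 2 or without treated replicate 1 or 4. Fatty acid and triglyceride synthesis genes were not called (23 of 24 measured, 15 higher and 8 lower, median log2 difference 0.05, camera adjusted p = 0.913), and without control replicate 4 the median was 0.13 (adjusted p = 0.05005, just above the threshold). The median was 0.03 without control replicate 1 or 2. In that list Insig2, a relative of Insig1, fell by 0.49 ± 0.10 over the list alone. Fasn, the fatty acid synthase, was higher by 0.31 ± 0.10, Acaca by 0.27 ± 0.09, and Agpat2 differed by -0.18 ± 0.05, none of the last 3 passing.

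Stellate cell and fibrosis genes, which hepatic stellate cells express when they lay down matrix, were higher in treated livers in 18 of the 22 members measured (24 listed), with a median log2 difference of 0.46. Over the list alone 8 members rose, 1 fell and 13 did not pass, with 0 past the threshold over all genes. Col1a1, a chain of type I collagen, was at 6.97 ± 0.06 in control and 8.59 ± 1.00 in treated livers (n = 4 each), a 3.08-fold difference. Col3a1 rose by 1.22 ± 0.35 and the matrix metalloprotease gene Mmp2 by 1.24 ± 0.32, whereas Reln fell by 0.29 ± 0.09. The treated livers differed widely among themselves. Col1a1 was at 8.09, 7.65, 9.96 and 8.68 in treated replicates 1 to 4. The list score was 0.92 in treated replicate 3, 0.34 in treated replicate 4 and -0.08 and -0.15 in the others. Camera called the list (adjusted p = 1.11e-06), with an adjusted p of 0.473 with an estimated correlation and an exact two-sided permutation p of 0.0571 for the scores. Without treated replicate 3 the median log2 difference was 0.22 and 6 members rose over the list alone. The number that rose was 0 without control replicate 1, 3 or 4 or without treated replicate 4, 4 without control replicate 2, and 12 without treated replicate 2.

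Camera also called 2 lists of markers of other liver cell types, in which the groups' scores overlapped. Macrophage and Kupffer cell markers were higher in 21 of 23 members measured (24 listed), with a median log2 difference of 0.30 (camera adjusted p = 7.06e-06, adjusted p = 0.468 with an estimated correlation, exact two-sided permutation p = 0.143 for the scores), and 0 passed over the list alone. The Kupffer cell genes Cd5l, at 8.93 ± 0.66 in control and 9.69 ± 0.53 in treated livers, and Timd4, 0.69 ± 0.30 higher, and the macrophage genes Mpeg1 (0.80 ± 0.25) and Gpnmb (0.31 ± 0.10) were among them. Without control replicate 3, whose macrophage score of -0.60 was the lowest of the 8 livers, the median was 0.16 and Cd5l differed by 0.44 instead of 0.76. Without treated replicate 1, Timd4 differed by 0.39. Over the list alone, 3 members passed without treated replicate 2 and 1 without control replicate 1. Liver sinusoidal endothelial markers were lower in 14 of 15 members, with a median log2 difference of -0.20 (camera adjusted p = 9.70e-05, adjusted p = 0.515 with an estimated correlation, exact two-sided permutation p = 0.257 for the scores), and 0 passed over the list alone. The C-type lectin gene Clec4g differed by -0.53 ± 0.19, the angiopoietin receptor gene Tek by -0.33 ± 0.12 and the scavenger receptor gene Stab1 by -0.20 ± 0.07.

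Inflammatory cytokine and NF-kB target genes were higher in 15 of 21 members, with a median log2 difference of 0.07 (camera adjusted p = 0.0374, adjusted p = 0.572 with an estimated correlation, exact two-sided permutation p = 0.286 for the scores), and 0 passed over the list alone. The monocyte chemokine gene Ccl2 differed by 0.27 ± 0.09, while Ccl7, at 4.28 in control livers, was no brighter there than the negative control rows. The call was lost without control replicate 3 (median 0.01, adjusted p = 0.384), without treated replicate 1 (median 0.07, adjusted p = 0.0913) and without treated replicate 3 (median 0.07, adjusted p = 0.195), the last 2 with hardly any move of the median. The median was 0.16 without treated replicate 2. Neutrophil markers were not called (13 of 13 measured, 2 higher and 11 lower, median log2 difference -0.27, camera adjusted p = 0.207), and the list depended on single livers. The neutrophil score was 1.25 in control replicate 1 against -0.35 to -0.13 in the other controls, and without it the median was 0.07 and the list was called higher (adjusted p = 0.0336). Without control replicate 3 it was called lower (-0.37, adjusted p = 0.0231). Elane, Mmp8 and Retnlg, genes of neutrophil granules and of neutrophils, were at 5.52, 4.80 and 5.63 in control replicate 1. Lymphocyte and NK cell markers were not called (18 of 21 measured, median log2 difference 0.05, camera adjusted p = 0.117), but were called higher without control replicate 4 (median 0.13, adjusted p = 1.88e-06), while the median was 0.01 without treated replicate 1 and 0.03 without control replicate 3.

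Circadian clock genes were lower in 16 of 19 members measured (20 listed), with a median log2 difference of -0.10 (camera adjusted p = 0.0279, adjusted p = 0.374 with an estimated correlation, exact two-sided permutation p = 0.0857 for the scores). Clock, a core activator of the circadian loop, fell by 0.27 ± 0.05 over the list alone and 18 members did not pass. The call was lost without treated replicate 1, where the median was -0.05 and the adjusted p 0.263. It was also lost with arrays centred on their medians (adjusted p = 0.0629) and with genes below the median level left out (adjusted p = 0.0669). The median was -0.06 without control replicate 1 and -0.16 without treated replicate 3. Genes of the p53 and DNA damage response were higher in 15 of 18 members measured (20 listed), with a median log2 difference of 0.09 (camera adjusted p = 0.00229, adjusted p = 0.111 with an estimated correlation, exact two-sided permutation p = 0.0571 for the scores). Sesn1, a stress-induced sestrin gene, rose by 0.33 ± 0.07 over the list alone and 17 members did not pass. Without treated replicate 3 the list's adjusted p was 0.0696. Sex-biased and growth hormone dependent genes were not called (27 of 30 measured, 9 higher and 18 lower, median log2 difference -0.04, camera adjusted p = 0.0544). They were called lower without control replicate 1 (-0.07, adjusted p = 0.00169), treated replicate 2 (-0.09, adjusted p = 0.00876) or treated replicate 3 (-0.07, adjusted p = 0.0371). In that list Cish, a feedback inhibitor that STAT5 induces, fell by 1.20 ± 0.24 over the list alone, from 7.97 ± 0.46 in control to 6.78 ± 0.36 in treated livers (n = 4 each). Bcl6, a repressor that opposes STAT5, was higher by 1.24 ± 0.41 without passing.

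Published targets of miR-128-3p were not called as a group. Of 24 measured (28 listed), 13 were higher and 11 lower, with a median log2 difference of 0.02 and a camera adjusted p of 0.436. Fry pointed up without passing (adjusted p = 0.0734). With each array left out the median ran from 0.00071 to 0.026. Insig1 was the only member past the threshold over the list alone. The glutamate receptor gene Gria3 was higher by 0.32 ± 0.10 and Rxra, a partner of the liver X receptors, differed by -0.05 ± 0.06 (-0.10 to -0.03 with each array left out). The host genes of the microRNA, R3hdm1 and Arpp21, differed by -0.07 ± 0.10 and -0.0020 ± 0.044, and the probe sets of Mir128-1 and Mir128-2 by -0.16 ± 0.08 and 0.13 ± 0.12. Single arrays moved these: R3hdm1 was at -0.15 without control replicate 2 and -0.0099 without treated replicate 1, Mir128-1 at -0.09 without treated replicate 2 and Mir128-2 at -0.0021 without treated replicate 1. Arpp21, at 3.47 in both groups, and Mir128-2, at 4.22 in control livers, were no brighter than the negative control rows. Such probe sets do not tell the level of the mature microRNA.

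**Figure D3:**
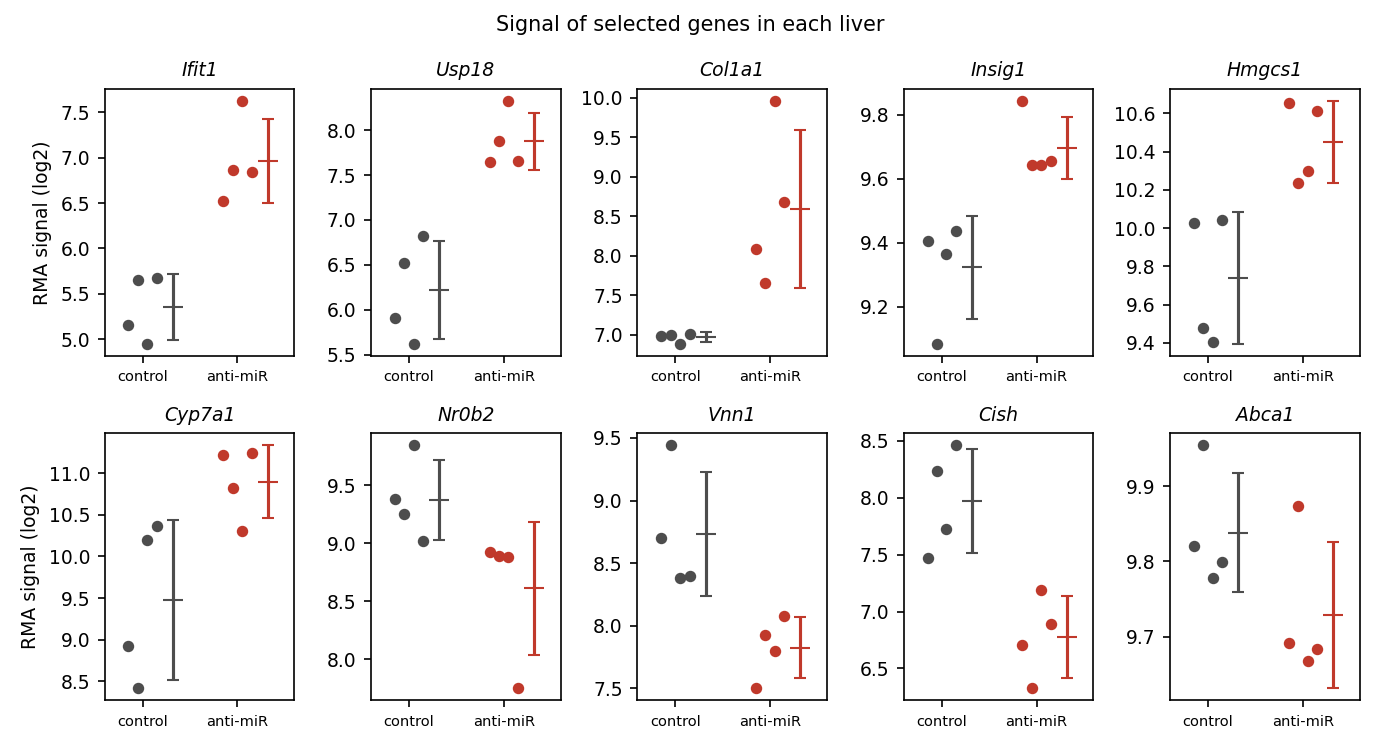
RMA log2 signal of 10 genes in each liver (vertical axis, own scale for each gene), with a point for each liver and bars for the group mean ± SD (n = 4 control and 4 anti-miR-128-3p). Ifit1 and Usp18 did not overlap between groups, Col1a1 reached 9.96 in treated replicate 3, and Nr0b2 was at 7.75 in treated replicate 4.

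The remaining lists were not called by camera with all 8 arrays, but 5 of them were called when 1 array was left out. Xenobiotic metabolism genes had a median log2 difference of -0.07 (adjusted p = 0.0732), hepatocyte markers -0.04 (adjusted p = 0.117) and genes of glucose metabolism and insulin signalling -0.04 (adjusted p = 0.207). Cholangiocyte markers had a median of -0.02 (adjusted p = 0.321), acute phase genes 0.06 (adjusted p = 0.391), muscle and pancreatic acinar markers -0.03 (adjusted p = 0.427) and cell cycle genes -0.04 (adjusted p = 0.555). Adipocyte markers had a median of -0.02 (adjusted p = 0.682), NRF2 oxidative stress genes 0.05 (adjusted p = 0.723) and erythroid markers 0.0018 (adjusted p = 0.913). Several of these lists had few members brighter than the highest array median of the negative control rows. They were 6 of 13 muscle and acinar, 6 of 9 cholangiocyte and 4 of 8 adipocyte markers measured. Of 12 erythroid markers listed, 7 were measured. Medians near 0 in these 4 lists say little. Xenobiotic metabolism genes were called lower without control replicate 1 (-0.23, adjusted p = 0.000444), control replicate 4 (-0.06, adjusted p = 0.0311) or treated replicate 3 (-0.19, adjusted p = 0.0158). Hepatocyte markers were called lower without treated replicate 2 (-0.05, adjusted p = 0.0491) or 3 (-0.05, adjusted p = 0.0449), and glucose genes without control replicate 1 (-0.08, adjusted p = 0.0259) or treated replicate 2 (-0.10, adjusted p = 0.0430). Other arrays brought these lists close to 0: without control replicate 3 the medians were -0.03 for xenobiotic, -0.0053 for hepatocyte and -0.0073 for glucose genes. Without treated replicate 1 the glucose median was -0.0026, without control replicate 4 it was -0.02, and the hepatocyte median was -0.01 without treated replicate 4 and -0.02 without control replicate 4. Acute phase genes were called higher without control replicate 1 (0.22, adjusted p = 1.42e-07) and had a median of -0.04 without control replicate 3 or 4 and -0.02 without treated replicate 3. Cell cycle genes were called lower without control replicate 3 (-0.06, adjusted p = 0.0208) and higher without control replicate 4 (0.05, adjusted p = 0.00419). In the list of ER stress and integrated stress response genes the median was 0.01 while the mean was -0.04 and the test pointed down (adjusted p = 0.819).

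The first principal component held 24.2% of the variance of the 15317 brighter genes and the second 20.4%. Scores on the first component did not overlap between groups (exact two-sided permutation p = 0.0286): control livers lay between -15.6 and -3.03 and treated livers between 0.93 and 21.1, with treated replicate 2 nearest to the controls. Mean correlations with the own group and with the other group were 0.995 and 0.993 for treated replicate 1, and 0.993 and 0.994 for control replicate 1. Control replicates 1, 2 and 4, 3 of the 4 controls, correlated slightly more with the treated livers than with the other controls (0.9938 and 0.9940 for replicate 2, 0.9939 and 0.9940 for replicate 4).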

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

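Of the tests in this part, those of the share of macrophages and of lymphocytes, of a single treated array, of ribosomal protein parent genes and of each list's splits were chosen after the result was seen, while the tests of stellate cells, of signal brightness and of the splits for the counts of genes and lists were set before.

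Several livers lay far from the other 3 of their group, past the 5% level of Dixon's test, in 18 of the 234 sets of 4 examined. Chance gives about 1 in 20 sets. The interferon score was 0.69 in treated replicate 3 against 0.21 to 0.29 in the other treated livers. The neutrophil score was 1.25 in control replicate 1 against -0.35 to -0.13, and the neutrophil genes Elane (5.52), Mmp8 (4.80) and Retnlg (5.63) stood apart in the same liver. Retnlg was also higher in treated replicate 3 (3.88) than in the other treated livers, below the medians of the negative control probe sets. The hepatocyte score was 0.071 in control replicate 3 against 0.0079 to 0.014 in the other controls. Among control livers, replicate 2 was high for Clcn2 (8.20) and Kdm6b (7.97), and replicate 3 was low for Col1a1 (6.88 against 6.99 to 7.01). Among treated livers, replicate 1 was high for Insig1 (9.84) and Mir128-2 (4.75), replicate 2 was high for Abca1 (9.87 against 9.67 to 9.69) and Cyp2u1 (8.67 against 7.62 to 7.66), replicate 3 was high for Ccl2 (5.56), and replicate 4 was high for Irgm1 (8.56) and low for Nr0b2 (7.75 against 8.88 to 8.92) and Amacr (9.68).

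The rise of interferon response genes in treated livers was set against 3 other sources: more macrophages, more lymphocytes and NK cells, or a single treated liver. The tables argue against more lymphocytes and NK cells only where these would raise both lists by the same amount. The interferon score minus the lymphocyte score was higher in treated livers by 0.66 (exact two-sided permutation p = 0.0286). With only the 11 of 18 lymphocyte markers above the negative control rows it was higher by 0.65 (exact two-sided permutation p = 0.0286). The median log2 difference of the lymphocyte markers was 0.05 with all arrays and 0.13 without control replicate 4 (camera adjusted p = 1.88e-06). A smaller rise of these cells, or a signal from them to other cells, cannot be told from these scores. Macrophages stay open: the interferon score minus the macrophage score was higher by 0.38 (exact two-sided permutation p = 0.0857). Without treated replicate 3 the mean difference was 0.63 against 0.73 with it (exact permutation p = 0.0571 two-sided and 0.0286 one-sided), and the control SD was 0.30. The other 3 treated scores, 0.21 to 0.29, lay above all 4 control scores, the highest of which was -0.03. In these values the rise was not confined to that liver, but by the two-sided p, which did not pass, a single liver stays open. Of the 35 splits of the 8 arrays into 4 and 4, only the real split, 1 of 35, gave so large a mean shift of the list, 0.73 against 0.62 at most in the others, but 1 of 35 is the smallest share there can be and the exact permutation p adjusted over the 28 lists was 0.30, so chance assignment is not excluded for a list picked among them. A reaction to the injected oligonucleotide and a loss of miR-128-3p activity also stay open and untested, since no group named in the labels got an unrelated antisense oligonucleotide.

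The higher collagen and fibrosis genes in treated livers were set against a single liver and against more stellate cells. For the 6 collagen genes, whose median log2 difference was 1.01, a single liver is argued against, since without treated replicate 3 the mean difference of their score was 0.67 against 0.97 with it (exact two-sided permutation p = 0.0286). For the list as a whole it stays open, because without that liver the mean difference was 0.29 against 0.51 with it (exact two-sided permutation p = 0.0571). More quiescent stellate cells as the whole source of the collagen rise are argued against by 9 genes of their identity. Of these, 2 are also in the fibrosis list. All 9 had a mean above 4.48, the highest array median of the negative control rows. Their median log2 difference was 0.02 with 5 of them higher, and the collagen score minus their score was higher in treated livers (exact two-sided permutation p = 0.0286). For that difference treated replicate 2, at -0.15, lay just above control replicate 2, at -0.17. A small rise of quiescent cells is not excluded. More stellate cells that lay down matrix stay open, since genes of quiescent cells cannot tell of them. Of the 35 splits, 2 gave as large a mean shift of the fibrosis list, 0.514 in the real split and 0.518 in another, so chance assignment cannot be excluded, and an effect of the treatment stays open as well.

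Ribosomal protein pseudogenes were higher in treated livers, a group chosen after its values were seen: 187 of 205 were higher, with a median log2 difference of 0.14 (0.13 with quantile normalization or arrays centred on their medians) and 96 at an unadjusted p under 0.05. A shift of all probe sets of that brightness is argued against, since random sets matched on level had a median of -0.0085. None of 10000 sets reached 0.14, the highest being 0.03. The sets held unrelated genes, so their narrow spread does not measure chance for related genes such as these. Probe sets that also read the parent transcripts may be the source, because the 44 ribosomal protein genes themselves were higher by a median of 0.12, 37 of them higher, with an exact two-sided permutation p of 0.0286. Of the 35 splits only the real split, 1 of 35, gave so large a mean difference of the pseudogenes, 0.16 against 0.09 at most in the others, but the group was picked because it was higher, so this does not exclude chance assignment. Why the parent genes were higher was not tested.

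The criterion for a single treated liver was changed several times after its values were seen. It was first that the other 3 treated scores all lie above the controls, then also that the two-sided exact p be under 0.05, then the first alone, and it is now the two-sided exact p. The first compares the other 3 treated scores with the controls and does not use treated replicate 3 itself. By the two-sided exact p the interferon list stays open, as given, whereas by the first criterion (gap of 0.24) a single liver would be argued against. By the first criterion the verdicts for the collagen genes (gap of 0.21) and the fibrosis list (gap of -0.0092) would be as given.

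Other splits of the arrays were as rich in calls as the real split for most results. The real split gave 0 genes past the adjusted threshold, a count that all 35 splits reach by necessity (the highest other gave 1), so it says nothing about chance. Of the 35 splits, 3 gave as many genes at an unadjusted p under 0.05 (2337 in the real split and 2871 at most in another) and 15 gave as many called lists (11 in the real split and 17 at most in another), so chance assignment cannot be excluded for these 2 counts. Apart from the interferon list, the cholesterol efflux list was the only called list for which 1 of 35 splits, the real split, gave so large a mean shift (0.107 against 0.098 at most in the others), and as its exact permutation p adjusted over the 28 lists was 0.30, chance assignment is not excluded for it. As large a mean shift came from 2 of 35 splits for the lipid droplet list (0.217 in the real split and 0.236 at most in another) and the p53 list (0.085 and 0.088), 3 for fatty acid oxidation (0.198 and 0.263) and the circadian clock (0.123 and 0.144), 5 for cholesterol synthesis (0.404 and 0.553) and macrophages (0.356 and 0.462), 9 for sinusoidal endothelium (0.213 and 0.378) and 10 for inflammatory cytokines (0.130 and 0.198). Chance assignment cannot be excluded for those lists.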

How the results depend on the processing

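Alternatives were planned, except for leaving out control replicate 1 and treated replicate 3 together and the exact permutation of list scores, which were chosen after seeing the data. None of the 89 named genes passed the threshold in the main fit, and only Irgm1 passed under an alternative run on them. That the others stayed uncalled says nothing of how firm their differences are. The named genes kept their directions except those given here. The count of genes past the threshold, 0, was 1 without control replicate 4 (range 0 to 1 with each array left out) and 0 under the other fits. It was 125 at an unadjusted p under 0.05 with at least 1.5-fold (97 higher and 28 lower). The 2337 genes at an unadjusted p under 0.05 became 1512 with genes below the median level left out and 4355 with every probe set by itself, where fewer and more features were tested, and 1718 to 2608 with each array left out. Centring arrays on their medians gave 1089 higher and 1174 lower, against 1305 and 1032. With the replicate number as a block, 0 genes and 14 lists were called, the bile acid, xenobiotic and sex-biased lists among them, and 2252 genes had an unadjusted p under 0.05. Same-numbered livers did not deviate together (correlations of -0.04, -0.04, -0.11 and -0.15), so the numbers do not pair them. Of the 11 called lists, 0 were called with an estimated correlation, 1 by fry and 0 by exact permutation with adjustment over the lists (smallest adjusted p 0.30). Medians are the same under those tests: 0.59 for interferon, -0.20 for fatty acid oxidation and for sinusoidal endothelium, 0.36 for cholesterol synthesis, 0.46 for fibrosis, 0.30 for macrophages, -0.22 for lipid droplets, -0.11 for cholesterol efflux, 0.094 for p53, -0.10 for the clock and 0.074 for inflammatory cytokines. With each array left out, 9 to 17 lists were called (17 without control replicate 1, and 15 with both arrays left out), and the medians ran from 0.068 to 0.11 for p53, from -0.16 to -0.046 for the clock and from 0.013 to 0.16 for inflammatory cytokines. The last 3 lists lost their calls elsewhere too: the clock list with dim genes left out (-0.15) and with centred arrays (-0.11), inflammatory cytokines with dim genes left out (0.20) and with both arrays left out (0.047), and p53 with both left out (0.087). The cause was not tested. The other 8 called lists kept direction and call under every other alternative run on them.

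Lists and genes not called reversed as follows, and the cause was not tested. With dim genes left out, ER stress was -0.0051 and published targets -0.0061. With quantile normalization, erythroid markers were -0.012, hepatocyte markers 0.0075, ER stress -0.0096 and Arpp21 0.0011. With centred arrays, erythroid markers were -0.0097 and ER stress -0.00034. With both arrays left out, neutrophil markers were 0.064, cholangiocyte markers 0.0079, muscle and acinar markers 0.019, NRF2 genes -0.047, Arpp21 0.023 and Mmp8 0.0054. With each array left out the ranges were -0.37 to 0.070 for neutrophil markers, -0.026 to 0.018 for erythroid markers, -0.038 to 0.0088 for adipocyte markers, -0.053 to 0.032 for muscle and acinar markers, -0.0037 to 0.087 for NRF2 genes, -0.027 to 0.011 for Arpp21 and -0.37 to 0.0079 for Elane. They were also -0.38 to 0.016 for Mmp8, -0.67 to 0.054 for Retnlg, -0.045 to 0.22 for acute phase genes, -0.028 to 0.034 for ER stress, -0.062 to 0.046 for cell cycle genes and -0.0021 to 0.19 for Mir128-2. What signal over background limits: no detection call was held, and genes near the array medians of the negative control probe sets (4.32 to 4.48), such as Arpp21, Mir128-2, Mmp8 and Retnlg, have differences that say little. The seed-site alternatives were not run, since no 3' UTR sequences were used here.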

Other observations

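The genes and groups of this part were chosen after their values were seen, and none of the genes passed limma's adjustment over all 30633 genes. Further interferon-induced genes outside the fixed list were higher in all 4 treated livers than in any control liver: Xaf1 by 1.28 ± 0.25 (log2 difference ± SE), Oas1g by 1.19 ± 0.22 and Zbp1, a sensor of Z-form nucleic acids, by 1.10 ± 0.24. On the lower side, Onecut1, a transcription factor of hepatocytes and bile duct cells, had the largest difference among protein-coding genes at an unadjusted p under 0.05, with -1.80 ± 0.39, from 9.37 ± 0.46 in control to 7.57 ± 0.83 in treated livers. Slc25a30, a mitochondrial carrier gene, differed by -1.26 ± 0.30, Inhbe, an activin subunit gene of hepatocytes, by -1.02 ± 0.31, and Plvap, a gene of endothelial diaphragms, by -0.60 ± 0.12, each without overlap between groups.

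The ribosomal protein genes differed by little but evenly. Their score was between -0.09 and -0.04 in the 4 control livers and between 0.0045 and 0.10 in the 4 treated livers, the median log2 difference was 0.11 to 0.15 with each array left out, and 18 of the 44 had an unadjusted p under 0.05.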
